A study of Mus musculus with 6 samples.

How the data were processed

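The study measured miRNAs by small RNA sequencing of total RNA from 6 mouse testes, 3 per water bath temperature. The deposited table held read counts per mature miRNA and precursor locus, raw and not normalized per the file headers. Per the submitters' processing notes, cutadapt (a read trimmer), edgeR and the build mm9 were used, with no role stated. The counting program and the miRBase release are not given in the sources used here. The table's precursor coordinates equal GRCm38 miRNA genes of GENCODE M21 for 503 of 511 precursors with a locus, so coordinates are given as in the table and called GRCm38.

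The table had 792 rows for 700 mature miRNAs and 514 precursors, and 47 further lines were blank and are not analysed here. Every row named a miRNA. A total of 54 mature names stood on more than 1 row because their hairpin has several genomic copies. In 26 of them the rows were identical, in 28 they differed, and in 47 the row totals lay within 10% of each other, so the same reads were counted at several copies. By a rule fixed before the data were examined, identical rows counted once and other rows of a name were summed. Summing can double the level of a miRNA such as miR-26a-5p or let-7f-5p without changing its fold change. There were 10 mature sequences carried by more than 1 name, and counts of such names cannot be separated. Deposited totals were 1759713 to 2838646 counts per library, and joined totals 1706785 to 2731445. Pairs of replicates differed far beyond counting noise (chi-square over degrees of freedom at least 94.7), so each library counted as 1 sample.

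Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr defaults, TMM scaling, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjusted p under 0.05. Of the 700 miRNAs, 515 were tested and 185 were left out by the filter. The square root of the common dispersion was 0.306. Standard errors are the fitted log2 fold change divided by the root of the F statistic. CPM values are TMM-scaled. For the 18 lists, fixed before the data were examined with any arm and copy of a listed hairpin as a member, limma 3.58.1 camera was run on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, on the 17 lists with at least 3 tested members, and adjusted over them. Arm ratios were log2 of (5p + 0.5) over (3p + 0.5), tested in limma with trend. The shares of counts and totals were compared by two-sided exact permutation.

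Named miRNAs followed a rule fixed before the data were examined. Among miRNAs past the threshold, with separate groups and a mean of at least 10 CPM, these were the 10 with the largest change and the 5 with the highest mean in each direction. To them came up to 4 members of each list with the smallest p, and the 5 most abundant of all miRNAs, which made 92 names. Hairpins in the arm comparison, 9 miRNAs named only in the closing section, and miR-34c-3p, miR-132-5p, miR-140-5p, miR-466a-3p, miR-669a-3p and miR-669o-3p in the report were chosen after their values were seen.

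The edgeR step was tested on simulated counts for 510 miRNAs with 200 changed, drawn from the real means, totals and dispersions. It recovered 56.6% of the 2-fold and 98.0% of the 4-fold changes, and 3.14% of its calls were false. In simulated data a list moved by 1 log2 unit was called, and 3.65% of unmoved lists had p under 0.05 over 50 runs. With independent simulated miRNAs that figure says nothing of correlated members. Of 20 hairpins with a moved arm among 145, 16 were recovered with 0 unmoved ones called.

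Mature sequences were searched exactly in GENCODE M21 transcripts other than miRNAs, and those found in transcripts of at least 10 genes were called repeat-like. Intervals of count ratios are exact binomial and cover counting error only. Alternatives fixed in advance were RLE scaling, total counts, DESeq2 1.42.0, limma-voom, no filter, a filter at 10 CPM in 3 samples, the replicate number as a block, leaving out each library, rows kept apart, miRBase-named rows only, and a 2-fold threshold. For lists they were an estimated correlation, fry, the most abundant arm and both scalings, and for arms 5 added counts or at least 10 CPM. Alternatives for tables of normalized values were not needed, because the table held counts.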

Results

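Small RNA reads were counted over mature microRNAs (miRNAs, short RNAs cut from the 5p or 3p arm of a hairpin precursor) in whole testes of outbred ICR mice. The scrotum of each mouse had been held in a water bath for 25 min, at 33 °C in the control group and at 43 °C in the heat group, and the testes were taken after 7 days. Each group held 3 testes. The labels do not say that the testes came from separate mice, so the p-values measure the spread between these samples. After rows of the same mature name were joined, the libraries held 1706785 to 2731445 counts and 677 to 683 of the 700 mature miRNAs each. A count of 3, taken as the floor, was worth 1.10 to 1.76 in a library as CPM, the count scaled to the library total. Fold changes here are log2 of 43 °C over 33 °C with the standard error (SE). The 5 most abundant miRNAs were miR-34c-5p (−0.32 ± 0.27), miR-881-3p (−0.19 ± 0.42), miR-148a-3p (0.08 ± 0.32), miR-143-3p (1.12 ± 0.17) and miR-99a-5p (0.13 ± 0.25). Among these 5, only miR-143-3p passed the test in edgeR (Benjamini-Hochberg adjusted p = 0.00237).

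The first comparison asked which miRNAs differed between testes taken after a scrotal bath at 43 °C and testes taken after a bath at 33 °C. Among miRNAs with a mean of at least 10 CPM and separate groups, the largest rises were those of miR-709 (log2 fold change 5.27 ± 0.35, SE), miR-6240 (5.15 ± 0.63), miR-5121 (4.56 ± 0.49) and miR-12204-5p (3.56 ± 0.48), with 3 testes per group. At that level the largest falls were those of miR-3471 (−2.89 ± 0.21), miR-449a-3p (−2.79 ± 0.30), miR-1195 (−2.39 ± 0.32) and miR-298-5p (−2.32 ± 0.22). Among abundant miRNAs, miR-143-3p, a marker of smooth muscle and fibroblast-like cells, rose from 54302 ± 1488 to 118209 ± 16141 CPM (mean ± SD, n = 3), which was 2.18-fold. The broadly expressed miR-26a-5p rose from 15026 ± 139.7 to 28708 ± 1926 CPM, and miR-30d-5p fell from 11259 ± 1369 to 5226 ± 303 CPM, 2.15-fold. In total 146 of 515 tested miRNAs passed the edgeR quasi-likelihood test, 73 higher and 73 lower at 43 °C.

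At a mean of at least 10 CPM, the other large rises were those of miR-6239 (3.36 ± 0.48, adjusted p = 0.00178), miR-3473e (3.03 ± 0.33, adjusted p = 0.000533) and miR-3473b (2.86 ± 0.31, adjusted p = 0.000533) by edgeR with Benjamini-Hochberg adjustment. Smaller rises in the same test were those of miR-708-3p (2.44 ± 0.57, adjusted p = 0.0154), miR-7230-3p (2.34 ± 0.50, adjusted p = 0.00901) and miR-690 (2.29 ± 0.37, adjusted p = 0.00356). The other large falls at that level were those of miR-7230-5p (−2.17 ± 0.53, adjusted p = 0.0166), miR-615-3p (−2.14 ± 0.43, adjusted p = 0.00758) and miR-329-5p (−1.97 ± 0.38, adjusted p = 0.00701) in the same test. They were followed by miR-296-5p (−1.93 ± 0.30, adjusted p = 0.00237), miR-296-3p (−1.93 ± 0.30, adjusted p = 0.00237) and miR-3470a (−1.89 ± 0.24, adjusted p = 0.00142). The precursor of miR-615 lies in an intron of the homeobox gene Hoxc5. Those of miR-296 (chromosome 2, 174267047 to 174267125, minus strand, GRCm38) and miR-298 (chromosome 2, 174267504 to 174267585, minus strand) are neighbours. The 5 most abundant miRNAs that rose with separate groups were miR-143-3p (1.12 ± 0.17), miR-26a-5p (0.93 ± 0.16), miR-470-5p (0.86 ± 0.18), miR-202-5p (0.81 ± 0.25) and miR-16-5p (0.78 ± 0.24). The 5 most abundant that fell were miR-30c-5p (−0.65 ± 0.19), miR-30d-5p (−1.11 ± 0.19), miR-340-5p (−0.59 ± 0.18), miR-127-3p (−1.19 ± 0.25) and miR-30e-3p (−0.64 ± 0.21). In these ranks miR-26a-5p, miR-16-5p and miR-30c-5p have more than 1 precursor copy. Summing of rows can raise their level, but not their fold change. Among the named miRNAs that passed, control counts were lowest for miR-212-3p, miR-709 and miR-5121, with 10, 12 and 15 counts over the 3 control libraries, against 57, 459 and 340 counts at 43 °C. The ratio of summed counts, scaled by the totals, was 5.57 for miR-212-3p (exact binomial 95% interval 2.82 to 12.2), 37.4 for miR-709 (21.2 to 72.8) and 22.1 for miR-5121 (13.2 to 40.0), intervals that cover counting error only. Falls given below for miR-124-5p, miR-25-5p, miR-379-3p and miR-92a-1-5p rest on 11, 13, 16 and 23 counts over the 3 heat libraries. Their control libraries held 63, 82, 68 and 106 counts, and the lowest library of each held 3.

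The precursor of miR-709 was annotated in an intron of Rfx1 (chromosome 8, 84086099 to 84086186, plus strand, GRCm38), that of miR-6240 outside genes of its strand (chromosome 5, 114851948 to 114852064, plus strand), and that of miR-5121 in an exon of the ribosomal protein gene Rpl13a (chromosome 7, 45126918 to 45126991, minus strand), where its sequence also occurs in the small nucleolar RNA Snord33. The mature sequences of miR-709, miR-3471, miR-3470a and miR-3473b were found in other transcripts of 57, 34, 441 and 343 genes, so counts of these entries may include reads of other RNAs. The sequence of miR-3473e differs from that of miR-3473b only in its last bases. Their rises may therefore not be separate measurements, and the exact search does not clear miR-3473e of such reads. Among the miRNAs with large or abundant changes, calls in edgeR with Benjamini-Hochberg adjustment ended when 1 library was left out for miR-708-3p (without control 2 or 3, adjusted p up to 0.0556), miR-7230-5p (without control 3 or heat 2, adjusted p up to 0.0532) and miR-470-5p (without control 2 or 3, adjusted p up to 0.0644). They also ended for miR-16-5p (without any control, adjusted p up to 0.141, 0.112 with total counts) and miR-202-5p (without any control or heat 2, adjusted p up to 0.134, 0.102 with total counts). Among those that fell they ended for miR-30c-5p (without any control or heat 1 or 2, adjusted p up to 0.151, 0.0594 with total counts), miR-30e-3p (without any control or heat 1 or 2, adjusted p up to 0.216, 0.0606 with RLE scaling and 0.0594 with total counts) and miR-340-5p (without any control or heat 1 or 2, adjusted p up to 0.175). Groups did not overlap for any of the 146 miRNAs, and for 232 of the 515 tested, where chance gives 10% with 3 against 3. The count of 146 fell to 82, 72 and 73 without control replicate 1, 2 or 3. With total counts as the only scaling, 46 miRNAs were higher and 71 lower, so that 39.3% of calls were higher.

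**Figure D1:**
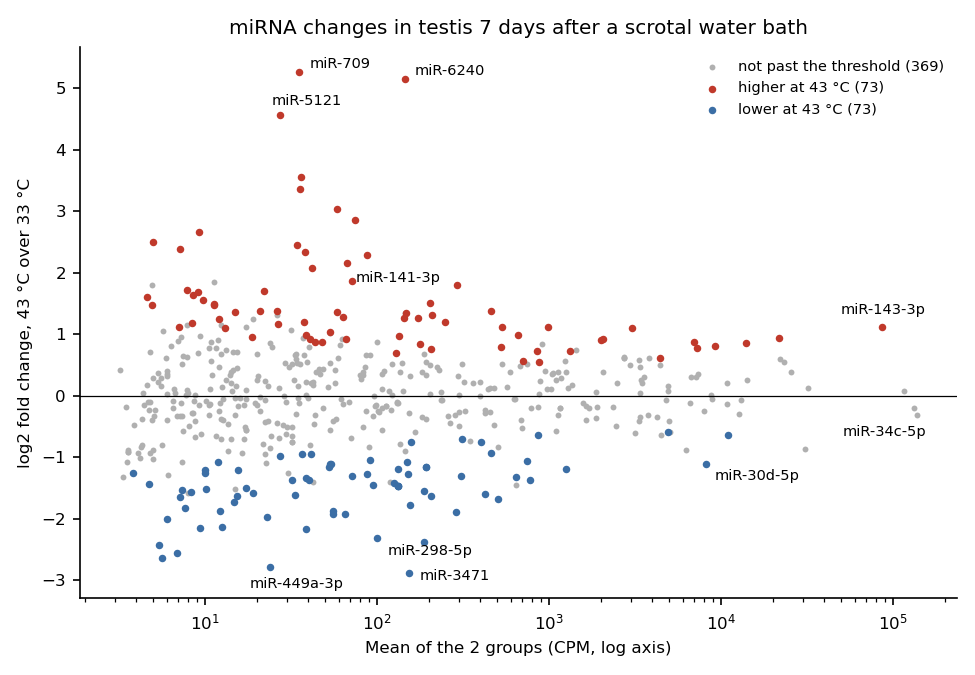
Log2 fold change of 43 °C over 33 °C against the mean level in CPM (log axis) for the 515 tested miRNAs, 1 point each. The 73 miRNAs that were higher are red and the 73 that were lower are blue. Entries with the largest rises lie below 1000 CPM, and miR-143-3p is the most abundant miRNA past the threshold.

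**Figure D2:**
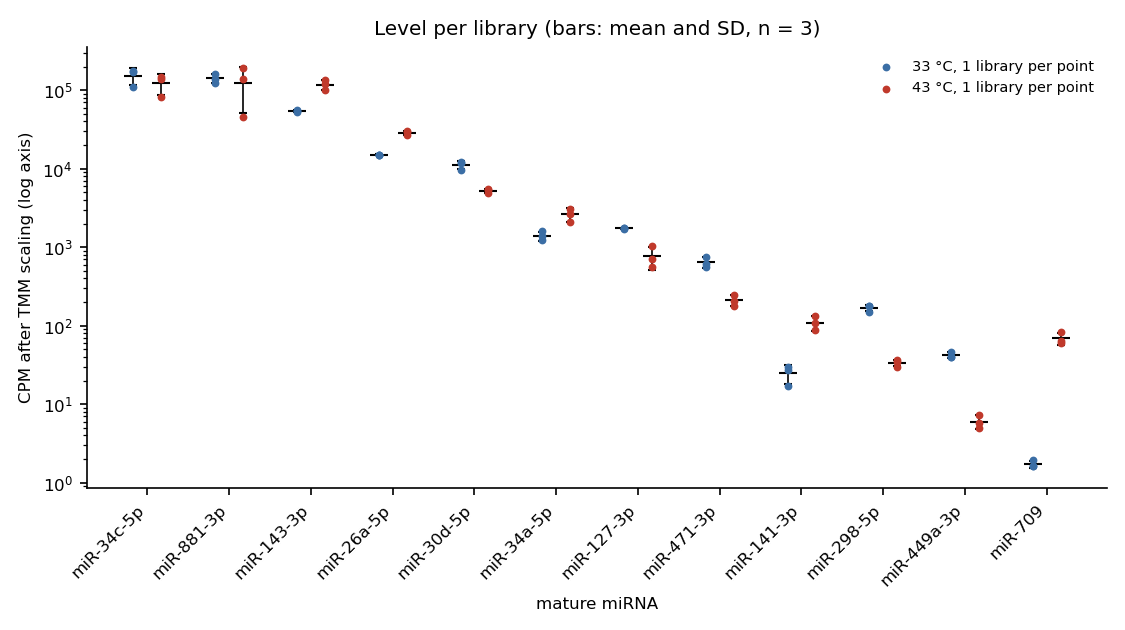
CPM per library (log axis) for 12 named miRNAs, with 33 °C libraries in blue and 43 °C libraries in red and bars for the mean and SD (n = 3). The 2 groups are apart for all but miR-34c-5p and miR-881-3p, whose libraries overlap.

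Few members of the germ cell lists passed, and none of the 4 lists passed as a group. Of 9 tested members of the meiotic and postmeiotic germ cell list, miR-449a-3p fell from 41.9 ± 3.62 to 6.01 ± 1.20 CPM (SD, n = 3), miR-449b rose from 15.8 ± 8.63 to 68.0 ± 8.08 CPM, and 7 did not pass, with the same counts adjusted over the list alone. Both come from 1 cluster in an intron of Cdc20b on chromosome 13. The fall was in the rarer arm of miR-449a, with a mean of 24.0 CPM over all libraries for miR-449a-3p. Its abundant partner miR-449a-5p, with a mean of 3483 CPM, had 0.21 ± 0.30 and was among the 7 that did not pass. The abundant members miR-34b-5p and miR-34b-3p, products of a hairpin expressed in spermatocytes and spermatids, had log2 fold changes of −0.87 ± 0.31 (edgeR Benjamini-Hochberg adjusted p = 0.0632) and −0.49 ± 0.20 (adjusted p = 0.0946). The arms of miR-34c had −0.32 ± 0.27 (miR-34c-5p, the most abundant) and −0.19 ± 0.28 (miR-34c-3p). In the X-linked cluster next to Fmr1, which is mostly expressed in testis, 4 were higher, 2 lower and 30 did not pass, with 3 higher and 2 lower adjusted over the list alone among 36 tested members. There, miR-470-5p (0.86 ± 0.18) and miR-742-3p (1.28 ± 0.25) rose, and miR-471-3p (−1.60 ± 0.21) and miR-743a-5p (−1.37 ± 0.20) fell. Among 10 tested members of the spermatogonial stem cell list, 1 was higher, 0 lower and 9 did not pass, with 1 higher and 0 lower adjusted over the list alone. The passenger arm miR-21a-3p (1.71 ± 0.41) rose, while its partner miR-21a-5p, at 17602 ± 1632 against 26669 ± 7620.5 CPM, had 0.60 ± 0.23 (adjusted p = 0.0800). Values for miR-222-3p (0.79 ± 0.29) and miR-182-5p (−0.23 ± 0.20) did not pass either. In the pluripotency miR-290-295 cluster, 0 were higher, 1 lower and 6 did not pass, with 0 higher and 0 lower adjusted over the list alone among 7 tested members. There miR-292a-5p fell (−1.08 ± 0.34), and miR-291a-3p (0.90 ± 0.30), miR-292a-3p (0.71 ± 0.34) and miR-295-3p (0.45 ± 0.31) did not pass.

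In limma camera, Benjamini-Hochberg adjusted p for these 4 lists was 0.339, 0.662, 0.339 and 0.662, and the median differences in log2 CPM were −0.33, −0.09, 0.20 and 0.16. Without 1 library these medians ranged from −0.58 (without heat 3) to −0.027 (without heat 2) for the meiotic and postmeiotic list and −0.16 (without control 3) to 0.14 (without heat 3) for the X-linked cluster. They ranged from 0.11 (without heat 3) to 0.33 (without heat 2) for the stem cell list and −0.0063 (without control 2) to 0.36 (without control 1) for the miR-290-295 cluster. For the X-linked cluster the median was below 0 while the mean (0.04) and the test pointed up. In edgeR with Benjamini-Hochberg adjustment, calls ended without 1 library for miR-21a-3p (without control 1 or 3, adjusted p up to 0.0719) and miR-292a-5p (without any control or heat 2 or 3, adjusted p up to 0.158, 0.0508 with RLE scaling). Members that passed only under an alternative, by adjusted p, were miR-34b-5p (0.0439 in DESeq2 and 0.0165 without heat 3), miR-34b-3p (0.0257 without heat 3) and miR-34c-3p (0.0335 without heat 3). The same was seen for miR-21a-5p (0.0465 in DESeq2 and 0.0157 without heat 3), miR-222-3p (0.0376 in DESeq2 and 0.0285 without heat 1) and miR-291a-3p (0.0468 with RLE scaling and 0.0409 without heat 3).

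Among the lists of other cell types, more members rose than fell, but no list passed as a whole. Of 18 tested members of the stromal and smooth muscle list, 6 were higher, 1 lower and 11 did not pass, with 6 higher and 1 lower adjusted over the list alone. Both arms of miR-143 rose, miR-143-5p from 255 ± 42.5 to 665 ± 36.1 CPM (SD, n = 3), with miR-99a-3p (1.69 ± 0.41), and the passenger arm miR-10b-3p (−1.37 ± 0.26) fell. Of 8 tested members of the Sertoli and Leydig list, 3 were higher, 0 lower and 5 did not pass, with 5 higher and 1 lower adjusted over the list alone. The cyclic-AMP-responsive neighbours miR-132-3p (1.38 ± 0.34) and miR-212-3p (2.50 ± 0.48) rose with miR-202-5p, a Sertoli cell miRNA that went from 6726 ± 895 to 11804 ± 3229.9 CPM. The other arm of miR-132, miR-132-5p, had −0.66 ± 0.29 and did not pass, and miR-140-3p (0.58 ± 0.22) and miR-140-5p (−0.58 ± 0.22) passed in opposite directions only over the list alone. The share of the 3p arm rose in miR-132, miR-212 and miR-140 (limma adjusted p = 0.0157, 0.0157 and 0.0222). Of 5 tested members of the erythroid list, 2 were higher, 0 lower and 3 did not pass, with 5 higher and 0 lower adjusted over the list alone. There miR-486a-5p (1.35 ± 0.30) and miR-486b-5p (1.27 ± 0.30) rose, 2 entries with 1 shared mature sequence on opposite strands of 1 locus that cannot be separated by reads. The red cell miRNAs miR-451a (0.84 ± 0.33) and miR-144-5p (0.86 ± 0.35) did not pass over all miRNAs.

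Of 9 tested members of the myeloid and lymphoid list, 2 were higher, 0 lower and 7 did not pass, with 3 higher and 0 lower adjusted over the list alone. The lymphocyte miRNA miR-150-5p (0.99 ± 0.27) and miR-146b-5p (0.55 ± 0.17) rose, and miR-142a-5p (0.67 ± 0.22) and the neutrophil miRNA miR-223-3p (0.79 ± 0.30) did not pass. Of 7 tested members of the epithelial miR-200 family, 2 were higher, 0 lower and 5 did not pass, with 2 higher and 0 lower adjusted over the list alone. Here miR-141-3p rose from 24.6 ± 6.77 to 109 ± 23.7 CPM and miR-200b-5p rose by 1.47 ± 0.45 on the log2 scale, while miR-200c-3p (0.82 ± 0.30) and miR-200a-3p (0.57 ± 0.24) did not pass. In the liver, muscle and neuron list, 1 was higher, 1 lower and 6 did not pass, with 3 higher and 1 lower adjusted over the list alone among 8 tested members. The muscle miRNA miR-133b-3p (1.55 ± 0.51) rose and miR-124-5p (−2.43 ± 0.41), an arm of a neuronal hairpin, fell, with miR-133a-3p (1.03 ± 0.37) and miR-1a-3p (0.74 ± 0.25) not past the threshold. The endothelial miR-126a-3p (0.20 ± 0.24) and miR-126a-5p (0.40 ± 0.29) did not pass, 0 of 2 tested members (also 0 adjusted over the list alone, and 0 with an unadjusted p under 0.05 in edgeR), and with fewer than 3 members had no list test.

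Median differences in log2 CPM were 0.31 for the stromal, 0.51 for the Sertoli and Leydig, 0.92 for the erythroid, 0.42 for the myeloid and lymphoid, 0.55 for the miR-200 and −0.28 for the liver, muscle and neuron list. Without 1 library the median ranged from 0.54 (without heat 2) to 1.21 (without heat 3) for the erythroid, 0.11 (without control 1) to 0.51 (without control 3) for the myeloid and lymphoid and −0.37 (without control 1) to 0.021 (without heat 1) for the liver, muscle and neuron list. The limma camera Benjamini-Hochberg adjusted p-values of the 6 lists were 0.135, 0.284, 0.0600, 0.382, 0.0600 and 0.910. The erythroid list passed without control replicate 2 (adjusted p = 0.0483), without heat replicate 3 (0.0270), with total counts (0.0340) and with the replicate block (0.0413). It did not pass with an estimated correlation (adjusted p = 0.708) or with 1 entry per mature sequence (adjusted p = 0.141). The miR-200 family passed without control replicate 1 (0.0374) or heat replicate 3 (0.0435). That family did not pass with an estimated correlation (adjusted p = 0.708). Calls of members ended without 1 library, in edgeR with Benjamini-Hochberg adjustment, for miR-99a-3p (without control 1 or 3, adjusted p up to 0.0772), miR-132-3p (without any control, adjusted p up to 0.0737) and miR-202-5p (without any control or heat 2, adjusted p up to 0.134, 0.102 with total counts). In the erythroid list they ended for miR-486a-5p (without control 3, adjusted p up to 0.0540) and miR-486b-5p (without control 1 or 3, adjusted p up to 0.0615). In the remaining lists they ended for miR-150-5p (without any control, adjusted p up to 0.110, 0.0697 with total counts) and miR-146b-5p (without any control or heat 1 or 2, adjusted p up to 0.162, 0.116 with total counts). They likewise ended for miR-200b-5p (without any control or heat 3, adjusted p up to 0.144, 0.0696 with total counts) and miR-133b-3p (without any control or heat 1 or 3, adjusted p up to 0.163, 0.0971 with total counts). Members that passed only under an alternative, by adjusted p, were miR-140-3p (0.0395 in DESeq2 and 0.0142 without heat 3) and miR-140-5p (0.0189 without heat 3). In the erythroid list they were miR-451a (0.0436 in DESeq2 and 0.00426 without heat 3) and miR-144-5p (0.0499 after thinning and 0.0196 without heat 3). Others were miR-142a-5p (0.0387 with RLE scaling, 0.0205 in DESeq2, 0.0300 with the GC offset, 0.0246 without heat 1 and 0.0412 without heat 3), miR-223-3p (0.0392 without heat 1) and miR-200c-3p (0.0342 in DESeq2). The remaining ones were miR-200a-3p (0.0258 without heat 3), miR-133a-3p (0.0251 in DESeq2 and 0.0315 without heat 2) and miR-1a-3p (0.0267 in DESeq2, 0.0283 with the GC offset and 0.00511 without heat 3).

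**Figure D3:**
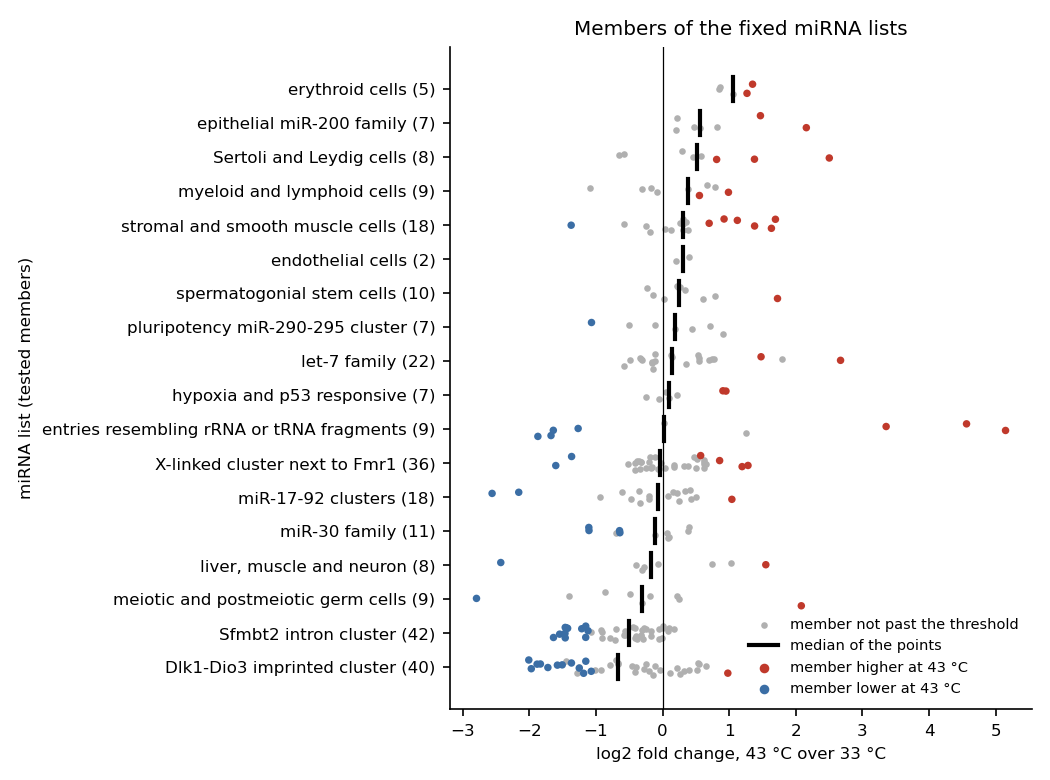
Log2 fold change of 43 °C over 33 °C for each tested member of the 18 lists fixed before the data were examined, with members past the threshold in colour and a bar at the median of the plotted points. The lowest medians are those of the Dlk1-Dio3 (−0.66) and Sfmbt2 (−0.50) clusters, and the highest is that of the erythroid list (1.06).

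Most members of 2 imprinted clusters did not pass, and nearly all that passed were lower at 43 °C. In the Sfmbt2 intron cluster on chromosome 2, rodent-specific repeats of related hairpins, 0 were higher, 11 lower and 31 did not pass, with 0 higher and 9 lower adjusted over the list alone among 42 tested members. Of these, miR-466b-3p (−1.55 ± 0.27), miR-466c-3p (−1.46 ± 0.28), miR-466e-3p (−1.47 ± 0.28) and miR-466p-3p (−1.46 ± 0.28) fell. The 11 lower members carry only 7 mature sequences, so their counts are not 11 separate measurements. miR-466b-3p, miR-466c-3p and miR-466p-3p share 1 sequence, miR-466a-3p and miR-466e-3p share another that contains it, and miR-669a-3p and miR-669o-3p also share 1. The calls of miRNA miR-669a-3p and miRNA miR-669o-3p ended without any control or heat 1 or 2 (edgeR Benjamini-Hochberg adjusted p up to 0.156) and with total counts (adjusted p = 0.0979). In the Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal allele, 1 was higher, 12 lower and 27 did not pass, with 1 higher and 12 lower adjusted over the list alone among 40 tested members. There miR-127-3p fell from 1739.9 ± 35.6 to 765 ± 248 CPM (SD, n = 3), with miR-379-3p (−2.01 ± 0.38), miR-329-5p (−1.97 ± 0.38) and miR-376b-3p (−1.88 ± 0.37). The median difference in log2 CPM was −0.52 for the Sfmbt2 list (limma camera, Benjamini-Hochberg adjusted p = 0.000454) and −0.82 for the Dlk1-Dio3 list (adjusted p = 0.00456), the only 2 of 17 tested lists to pass. Neither call held with an estimated correlation between members (adjusted p = 0.708 and 0.819) or in fry (adjusted p = 0.0640 and 0.198). The Dlk1-Dio3 call also ended with only the most abundant arm of each hairpin (adjusted p = 0.443). Without 1 library the median ranged from −0.54 (without control 1) to −0.32 (without heat 2) for the Sfmbt2 list. It ranged from −1.27 (without heat 2) to −0.63 (without heat 1) for the Dlk1-Dio3 list. The fall of that list was thus larger without heat 2 than with all libraries (−0.82).

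Among families found in most cell types, 4 members of the miR-30 family fell and few members of the others changed. In the miR-30 family, 0 were higher, 4 lower and 7 did not pass, with 0 higher and 4 lower adjusted over the list alone among 11 tested members. miR-30d-5p (−1.11 ± 0.19), miR-30b-3p (−1.10 ± 0.24), miR-30c-5p (−0.65 ± 0.19) and miR-30e-3p (−0.64 ± 0.21) fell. In the growth-promoting miR-17-92 clusters, 1 was higher, 2 lower and 15 did not pass, with 1 higher and 2 lower adjusted over the list alone among 18 tested members. There miR-17-3p (1.04 ± 0.26) rose. The passenger arms miR-25-5p (−2.56 ± 0.38) and miR-92a-1-5p (−2.16 ± 0.45) fell, and the abundant miR-25-3p had −0.61 ± 0.21 (edgeR Benjamini-Hochberg adjusted p = 0.0544). In the let-7 family, 2 were higher, 0 lower and 20 did not pass, with 2 higher and 0 lower adjusted over the list alone among 22 tested members. The passenger arms let-7g-3p (2.67 ± 0.54) and miR-98-3p (1.48 ± 0.37) rose, while let-7f-5p at 18899.6 ± 2657 against 27520.2 ± 4792 CPM (0.54 ± 0.20) and let-7k (1.80 ± 0.65) did not pass. In the hypoxia and p53 list, 2 were higher, 0 lower and 5 did not pass, with 2 higher and 0 lower adjusted over the list alone among 7 tested members. There miR-34a-5p, a direct p53 target, rose from 1395 ± 187 to 2614 ± 497 CPM and miR-215-5p rose (0.95 ± 0.30), while miR-194-5p (0.10 ± 0.22) and the hypoxia miRNA miR-210-3p (−0.25 ± 0.20) did not pass.

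None of these 4 lists passed in limma camera, with Benjamini-Hochberg adjusted p of 0.339, 0.556, 0.339 and 0.405 and median differences in log2 CPM of −0.12, −0.11, 0.04 and 0.10. The let-7 median changed sign with total counts only (−0.039). Without 1 library the medians ranged from −0.28 (without heat 3) to 0.017 (without heat 2) for the miR-30 family and −0.40 (without heat 3) to −0.042 (without heat 2) for the miR-17-92 clusters. They ranged from −0.14 (without heat 3) to 0.36 (without heat 1) for the let-7 family and −0.049 (without control 3) to 0.25 (without heat 2) for the hypoxia and p53 list. In edgeR with Benjamini-Hochberg adjustment, calls ended without 1 library for miR-30b-3p (without control 2, adjusted p up to 0.0598), miR-30c-5p (without any control or heat 1 or 2, adjusted p up to 0.151, 0.0594 with total counts) and miR-30e-3p (without any control or heat 1 or 2, adjusted p up to 0.216, 0.0606 with RLE scaling and 0.0594 with total counts). They also ended for miR-17-3p (without control 1 or 2, adjusted p up to 0.0884) and miR-98-3p (without any control, adjusted p up to 0.0778), and for miR-34a-5p (without any control, adjusted p up to 0.0958) and miR-215-5p (without any control or heat 1 or 2, adjusted p up to 0.147, 0.0762 with total counts). Only under an alternative did miR-25-3p (0.0416 with total counts, 0.0412 in DESeq2, 0.0400 in limma-voom and 0.0433 without heat 1), let-7f-5p (0.0412 in DESeq2, 0.0405 with the GC offset, 0.0496 without heat 1 and 0.0443 without heat 3) and let-7k (0.0279 without heat 1) pass, by adjusted p.

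Entries listed in advance as possible fragments of longer RNAs, ribosomal or transfer RNA among them, moved both ways. Of 9 tested members of that list, 3 were higher, 4 lower and 2 did not pass, with 4 higher and 4 lower adjusted over the list alone. miR-6240 rose from 7.75 ± 3.99 to 283 ± 201 CPM, miR-5121 from 2.13 ± 0.634 to 52.3 ± 23.3 CPM and miR-6239 from 6.13 ± 3.65 to 65.2 ± 21.8 CPM (SD, n = 3), and miR-5099 fell from 775 ± 83.6 to 243 ± 74.2 CPM. In the exact search of GENCODE M21 transcripts only miR-5121 matched other transcripts, those of Rpl13a and Snord33. No separate set of ribosomal or transfer RNA sequences was searched, so an origin of the members in those RNAs was not tested. The list as a whole did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.662, median difference 0.14 log2 CPM, from −0.28 (without control 1) to 0.52 (without control 3) without 1 library).

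The ratio of the 2 arms of a hairpin does not depend on scaling between libraries, and it asked whether arms moved apart. By the sign of the group means, the more abundant arm was not the same in both groups in 12 hairpins that passed. Log2 of 5p over 3p was 2.38 ± 0.48 at 33 °C and −2.31 ± 0.85 at 43 °C for miR-7230 (SD, n = 3), −0.92 ± 0.30 and 1.05 ± 0.21 for miR-322, and −0.26 ± 0.09 and 1.60 ± 0.21 for miR-376b. Both means also lay more than 1 SD from 0 for miR-136 (−0.61 ± 0.08 and 0.44 ± 0.24) and miR-28a (0.52 ± 0.13 and −0.44 ± 0.04). The same held for miR-324 (−0.52 ± 0.11 and 0.68 ± 0.29), miR-671 (−0.32 ± 0.28 and 2.30 ± 1.19) and miR-212 (1.67 ± 0.66 and −0.45 ± 0.41). Less clear, with a group mean within 1 SD of 0, were miR-674 (0.03 ± 0.47 at 43 °C), miR-132 (−0.60 ± 0.88 at 43 °C), miR-463 (−0.17 ± 0.23 at 43 °C) and miR-742 (0.12 ± 0.23 at 33 °C). The 5p share rose for miR-449a (change 2.90 ± 0.31, SE), miR-322 (1.97 ± 0.22), miR-195a (1.82 ± 0.19), miR-10b (1.64 ± 0.17), miR-376b (1.86 ± 0.30) and miR-471 (1.43 ± 0.21). The 3p share rose for miR-130b (−2.25 ± 0.36), miR-25 (−1.88 ± 0.27) and miR-201 (−1.51 ± 0.20). These values are changes of a log2 ratio, so where 1 arm was rare its share moved little. From 33 °C to 43 °C the log2 ratio went from 6.26 to 9.16 for miR-449a, 7.79 to 9.43 for miR-10b and −8.31 to −10.2 for miR-25. The rare arm miR-25-5p had 82 counts over the 3 control and 13 over the 3 heat libraries. In all, 49 of 147 hairpins passed in limma (Benjamini-Hochberg adjusted p = 0.000937 for miR-7230 and 0.00530 for miR-376b), 28 toward the 5p and 21 toward the 3p arm, and the less abundant arm lost share in 26 and gained in 23. Both arms passed the edgeR test singly in 8 hairpins, in 1 direction in 7 of them and in opposite directions in miR-7230 alone. The 10 hairpins with the smallest p, and those of the Sertoli and Leydig list, were chosen after their values were seen. The count fell to 16 without control replicate 1 and to 19 without control replicate 2.

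**Figure D4:**
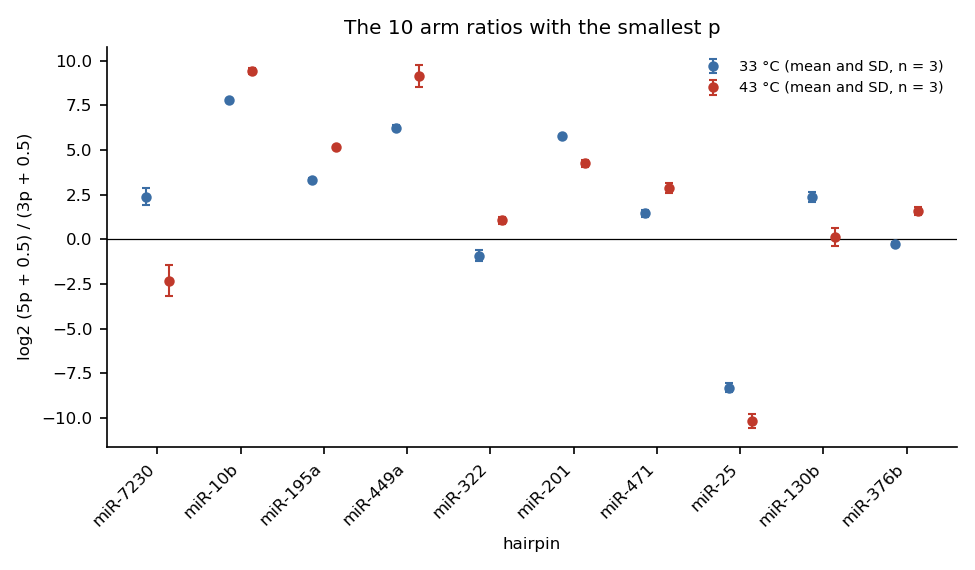
Log2 of (5p + 0.5) over (3p + 0.5) counts for the 10 hairpins with the smallest p, as mean and SD of 3 libraries at 33 °C (blue) and 43 °C (red). miR-7230 lies at 2.38 ± 0.48 in the control group and at −2.31 ± 0.85 in the heat group.

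Library composition was compared last, as a description of the libraries. The 10 most abundant miRNAs held 62.2% ± 1.81 of counts at 33 °C and 62.8% ± 3.36 at 43 °C (SD, n = 3; two-sided exact permutation p = 0.80). The most abundant, miR-34c-5p, held 15.7% ± 3.20 and 12.0% ± 3.88 (exact permutation p = 0.30). Totals averaged 2260390 ± 517293 and 2314950 ± 517248 counts (exact permutation p = 0.90). With 3 against 3 the smallest p such a test can give is 0.10. On the first principal component, with 59.1% of the variance, the 3 libraries of each group lay together, and on the second, with 19.7%, heat replicate 3 stood apart from the other two libraries of its group.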

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

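The highest row per name, 1 entry per sequence, the GC offset, thinning to the smallest total and leaving out fragment-like entries were chosen after the data were seen. Over alternatives that kept all libraries, 112 to 168 miRNAs passed (146 as reported), and higher calls numbered 46 with total counts only. Leaving out 1 library gave 72 to 204 changed miRNAs, 29 to 98 higher and 42 to 106 lower. All 146 kept their direction wherever they were tested. Of the 64 named miRNAs that passed, 41 passed in each of the 6 fits without 1 library, 54 passed under both other scalings, and 0 reversed in any alternative. miR-146b-5p, miR-292a-5p, miR-30c-5p, miR-30e-3p and miR-340-5p did not pass with no filter and miR-30e-3p did not pass with the filter at 10 CPM. miR-200b-5p and miR-292a-5p did not pass in DESeq2 and miR-133b-3p did not pass in limma-voom. miR-30e-3p and miR-340-5p did not pass with the GC offset and miR-133b-3p, miR-292a-5p, miR-30c-5p, miR-30e-3p and miR-340-5p did not pass after thinning. miR-292a-5p, miR-30c-5p, miR-30e-3p and miR-340-5p did not pass without fragment-like entries. A 2-fold threshold left out 11 named calls. Of the 28 named miRNAs that did not pass, 17 passed under 1 or more alternatives, 11 of them in DESeq2 and 11 without heat replicate 3. miR-142a-5p passed also with the GC offset, without a filter, with the filter at 10 CPM, with either other choice of rows, with 1 entry per sequence and without fragment-like entries, and miR-291a-3p with the filter at 10 CPM and with rows kept apart. let-7k passed with the replicate block. The replicate numbers were not taken as pairs: correlations of same-numbered deviations were −0.34, −0.15 and 0.25, and only number 3 correlated best with its own number. With the replicate block, 127 miRNAs, 3 lists and 40 hairpins passed, the added list being the erythroid one (adjusted p = 0.0413), and miR-146b-5p, miR-16-5p, miR-202-5p, miR-215-5p, miR-292a-5p, miR-30c-5p, miR-30e-3p and miR-340-5p did not pass. Filtering to miRBase-named rows removed nothing and tests nothing. Lists past the threshold numbered 0 with an estimated correlation (0 with an unadjusted p under 0.05), 0 in fry (6 unadjusted), 1 with the most abundant arm and 2 to 4 without 1 library (4 without heat replicate 3). Arm ratios past the threshold numbered 16 to 52 without 1 library. The composition difference of 0.608 percentage points became −3.62 for the single most abundant miRNA, and ranged from −0.763 to 2.48 without 1 library. The causes were not tested. Fits without 1 library lose a sample, but their numbers of changed miRNAs also differed with the library left out. These were 82, 72 and 73 without control 1, 2 or 3 and 143, 125 and 204 without heat 1, 2 or 3.

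Signs changed only for values that did not pass as reported. With the most abundant arm, medians were −0.54 (miR-290-295), 0.82 (liver, muscle and neuron), 0.0096 (miR-17-92) and 0.034 (miR-30), and with total counts −0.039 (let-7). Without 1 library, medians ranged over −0.0063 to 0.36 (miR-290-295), −0.37 to 0.021 (liver, muscle and neuron), −0.28 to 0.017 (miR-30), −0.14 to 0.36 (let-7), −0.16 to 0.14 (X-linked cluster), −0.049 to 0.25 (hypoxia and p53) and −0.28 to 0.52 (fragment-like entries). The log2 fold change of miR-148a-3p was −0.031 with total counts, −0.028 in limma-voom and −0.025 with the replicate block, where that of miR-465b-5p was −0.43. For miR-465d-5p it was 0.018 with RLE scaling, 0.022 in DESeq2, 0.036 with no filter, 0.12 with the GC offset, 0.16 after thinning and 0.020 without fragment-like entries. That of miR-196a-5p was 0.55 in limma-voom and 0.13 with the replicate block. Ranges without 1 library were −0.19 to 0.41 for miR-148a-3p, −0.046 to 0.23 for miR-194-5p, −0.025 to 0.36 for miR-99a-5p, −0.61 to 0.21 for miR-881-3p, −0.83 to 0.28 for miR-196a-5p, −0.58 to 0.039 for miR-34c-3p (past the threshold at the lower end, without heat replicate 3, adjusted p = 0.0335), −1.03 to 0.65 for miR-465d-5p and −6.18 to 6.61 for miR-465b-5p. Depth limits the rarer entries: 22 of the 146 called miRNAs averaged under 10 CPM.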

Other observations

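The tests of fragment-like entries going 1 way, of somatic markers and of miR-465b-5p, and all miRNAs named in this part outside the fixed rule, were chosen after the values were seen, while the test of non-canonical entries and the splits of the libraries were fixed before. Both arms of miR-423 were lower at 43 °C, miR-423-5p (−1.79 ± 0.21, adjusted p = 0.000830) and miR-423-3p (−1.31 ± 0.18, adjusted p = 0.00154), as log2 fold change ± SE (n = 3) by edgeR with Benjamini-Hochberg adjustment. The neighbouring X-linked hairpins miR-322 and miR-503, which share the seed of the miR-16 family, gave higher miR-322-5p (1.12 ± 0.23, adjusted p = 0.00863) and miR-503-5p (1.81 ± 0.22, adjusted p = 0.00112). Over the alternatives run, these 4 miRNAs kept their direction and passed in each in which they were tested, and miR-16-5p, with 0.78 ± 0.24, did not pass without any 1 of the 3 control libraries.

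With 3 against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split gave 146 miRNAs and 49 arm ratios, 1 split in 10 for each, against a highest other value of 0 in both cases. For the lists the real split gave 2 and 8 of the 10 splits gave at least as many, the highest other being 6. The Sfmbt2 list passed in 4 of the 9 other splits (lowest adjusted p = 3.47e-08, limma camera) and the Dlk1-Dio3 list in 3 of them (lowest adjusted p = 1.12e-16). All 3 of these Dlk1-Dio3 splits set heat replicate 2 with 2 of the control libraries. Their number thus also reflects how heat replicate 2 differed from the other heat libraries.

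Entries such as miR-709, miR-6240 and miR-5121, which may stem from other RNAs, were among the largest changes. One hypothesis is that fragments of longer RNAs were counted as miRNAs, in which case non-canonical entries would pass more often. Entries the deposited table calls non-canonical passed in 45 of 124 cases (36.3%) and canonical ones in 101 of 391 (25.8%). The odds ratio was 1.63 (95% interval 1.03 to 2.56, two-sided Fisher's exact test p = 0.0296), as that hypothesis predicts, although miRNAs are not independent replicates. The label was not shown to mark fragments, so changes of non-canonical miRNAs themselves would give the same result. Degraded RNA in the 43 °C libraries would raise fragment-like entries together only if their sources broke down alike. Of the 15 tested fragment-like or repeat-like entries 5 rose and 7 fell, among them miR-5099 and miR-3471. The repeat-like ones alone gave 2 rises and 3 falls among 6. The entries thus did not rise together, but their sources may differ and RNA quality was not measured here, so degradation is not excluded. Without the fragment-like and repeat-like entries 129 miRNAs passed. What remains open is whether the RNAs behind them changed with temperature or with library preparation, which the tables do not separate.

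Several somatic markers rose, miR-143-3p by 1.12 ± 0.17 and miR-202-5p by 0.81 ± 0.25, which may reflect a lower share of germ cells at 43 °C. A lower share alone would move the somatic markers alike if they were absent from germ cells, which was not measured here. Of the most abundant arms of 26 hairpin names in the 5 somatic lists, 10 (38.5%) lay more than 2 SE from their weighted mean of 0.45. Among them were miR-486a-5p and miR-486b-5p, which share 1 sequence. Another was miR-145a-5p, transcribed beside miR-143, at −0.58 ± 0.24 (edgeR Benjamini-Hochberg adjusted p = 0.104, not past the threshold). The 26 were not all separate measurements or major arms. They held miR-125b-5p (mean 1898 CPM) with the rarer arm miR-125b-1-3p (46.8 CPM), and miR-199a-3p and miR-199b-3p at 0.305 each. Of the 26 arms, 8 passed as higher and 0 as lower. Without values from germ cells, this spread cannot decide whether a lower germ cell share was the sole cause. A change within single somatic cell types stays open, as an untested hypothesis.

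Some members of the miR-465 family in the X-linked cluster differed between libraries rather than between temperatures. miR-465b-5p had 36118 counts in control replicate 2 and 36253 in heat replicate 1, and 86 to 194 in the other 4 libraries, while miR-465c-5p, which differs from it in 1 of 22 bases, had 23518 to 35393 in all 6. The rarer miR-465d-5p had 94 and 98 counts in those libraries and 16 to 33 in the other 4. Reads shared with miR-465c-5p at the same rate in all libraries would keep 1 ratio of the pair, but the highest ratio (1.15) was 331 times the lowest (0.00348). Sharing in single libraries is not excluded. Counts of the pair were close in control replicate 2 (36118 and 35393) and heat replicate 1 (36253 and 31448). A sequence or copy difference between outbred mice stays open, as an untested hypothesis, since no genotype was analysed here. The same libraries, control replicate 2 and heat replicate 1, had the lowest miR-196a-5p counts (19 and 90, against 210 to 357).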
